A study of Mus musculus with 1417 samples.

How the data were processed

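Single-cell transcriptomes were measured in 1417 wells of an iCELL8 nanowell chip, a chip whose wells are imaged to find those holding a single cell before in-chip reverse transcription and amplification. The labels give the strain, the sort (negative for lineage antigens, CD24 and CD49f), the kind of well and its row and column on the chip, counted from 0 to 71. Reads were processed with TopHat and Cufflinks on mm10, per the submitters' processing notes. Versions and settings of these tools are not given in the sources used here.

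Each well has a deposited table of 34535 transcripts with FPKM (fragments per kilobase of transcript, scaled to the mapped reads of the well) and coverage as the authors' Cufflinks run wrote them, per the file headers. Both are normalized or derived values and not counts, and no molecular identifiers are described, so PCR copies are counted as reads. FPKM divided by the deposited coverage (a signal of reads per base) was constant within each well to a ratio of 1.000018, which gave the number of mapped reads. It came out whole in 1417 of 1417 wells, within 0.01 reads of 100 bases or, in deeper wells, a wider tolerance in proportion to the reads. Reads per transcript were taken as coverage times length over the read length, and used only for thinning and pooled profiles. They are estimates that Cufflinks spreads over isoforms, so no count model was fitted.

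FPKM was summed over the transcripts of each of 24346 gene symbols. FPKM is a share of a well's reads: a rise of 1 abundant gene lowers all others, and in a well of about 1543 reads a single read gives a high FPKM. A gene was called detected at an FPKM of at least 1. Before the data were examined, the following were fixed: S wells with at least 500 detected genes were kept, values were set to log2(FPKM + 1), and genes in at least 10 kept cells outside the function, background and gate lists could enter the clustering. The 2000 most variable of them gave 20 principal components, 15 nearest neighbours and Leiden clusters at resolution 1. No doublet caller was run, because the labels describe selection of single-cell wells by imaging and the tables hold no counts of molecules.

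Clusters were named from fixed marker lists by a rule set after the data were seen. A cluster took the name of another cell type if at least 3 of its markers were in at least 25% of the cells and raised at least 2-fold over the other kept cells. Otherwise it was called fibroblast-like if at least 3 fibroblast markers were in at least 25% of its cells, which every cluster met. Ties were read in alphabetical order of the list names. Of all listed symbols, Hbb-bt and Ly76 were absent from the tables.

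Function lists (21, with 362 genes) were compared between each fibroblast-like cluster and all other fibroblast-like cells as log2 of the ratio of mean FPKM + 1. The median of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins. This describes these cells and is not a test, since cells are not replicates and no animal is named. The named genes followed a rule fixed beforehand: a log2 ratio of at least 1 in size, a mean of at least 5 FPKM on the higher side, exact 95% intervals of the shares of cells that do not overlap, and the same direction in chip columns 0 to 35 and 36 to 71. Up to 4 genes per list and 30 per comparison were named, with Srd5a2, Cd24a, Itga6, Pecam1 and Ptprc among those always looked at. Positions are those of the tables, with 1 added to the start, which counts from 0 there.

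Parts of the procedure were tested on simulated data: 1170 cells with the real depths, of which 120 had 200 genes changed 4- or 8-fold and 1 list changed. The main cluster of the changed cells held 75.0% of them and was 96.8% pure. Lists and genes were compared between the changed cells as simulated and the others, not between the clusters found. There the changed list lay at percentile 100 and 0 of 20 unchanged lists lay outside. The 200 genes were drawn from those with a mean of at least 20 FPKM. Of these, 50 of 50 at each fold and direction had a log2 ratio of at least 1 on the right side. Clusters cut from the unchanged cells were also put to the size, mean and share parts of the rule for named genes. Over 5 such clusters, 5 list genes passed, although no gene had been changed in these cells. Their median depths ran from 7348 to 83623 reads on genes. The agreement between parts of the chip was not simulated. Depth limits the precision: 1100 of 1170 kept cells had 10000 reads on genes, to which cells were thinned where shares were compared, and 24 of 48 negative control wells had 1000.

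Alternatives covered the detection level, the minimum of genes, the pseudocount, rescaling, the clustering settings, the form of the ratio and the parts of the chip. Function lists and named genes kept the main clusters throughout, so they were not recomputed under other clustering settings. Further alternatives were added after the data were seen: another random start, histone and 5S rRNA copies left out, secretory genes removed, capped values, cells weighted by reads, clusters led by multicopy genes left out, and thinned wells. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.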

Results

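Single wells of a nanowell chip were profiled by polyA RNA sequencing to ask how stromal cells of the mouse prostate differ from each other. The cells came from C57Bl/6 mice and were sorted as negative for lineage antigens, CD24 and CD49f, so the sort was meant to take stroma and leave out blood, endothelium and epithelium. Each of 1417 samples was 1 well. The labels named 1323 of them with an S, 48 as negative control wells and 46 as positive control wells, and did not say what the positive control wells held. No animal was named, so the S wells were treated as 1 sample. Values are means or shares over cells without replicates, and exact (Clopper-Pearson) 95% intervals cover counting error only.

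S wells held far more RNA signal than either kind of control well. The median S well had 40678 mapped reads (range 845 to 315569) and 1153 detected genes. Negative control wells had a median of 1543 mapped reads (897 to 3729) and 267.5 detected genes, and positive control wells 1649 mapped reads (658 to 3504) and 282.5 detected genes. Positive control wells thus lay beside the negative control wells and far below the S wells. With at least 500 detected genes required, 1170 S wells were kept, a share of 88.4% (86.6 to 90.1). The same minimum was reached by 1 negative and 3 positive control wells, which never entered the clustering.

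**Figure D1:**
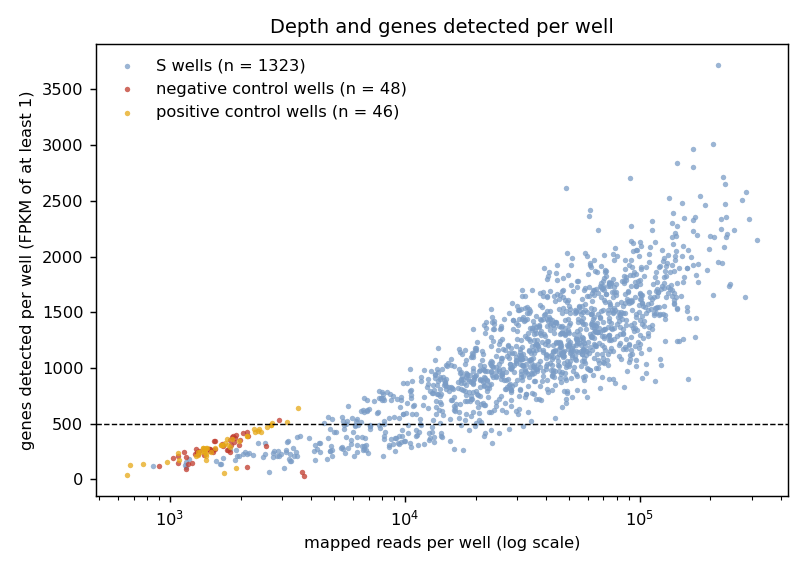
Genes detected per well at an FPKM of at least 1 against mapped reads per well on a log scale, 1 point per well, for S wells, negative control wells and positive control wells. The dashed line marks the 500 genes a kept S well needed; the control wells lie at 658 to 3729 reads and mostly below the line.

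Most kept cells took the name fibroblast-like, which was given to clusters without raised markers of another cell type. Dcn, a small matrix proteoglycan, was found in at least 96.3% of the cells of each cluster except cluster 6, with 85.3% (76.5 to 91.7). It does not set fibroblasts apart, since the epithelial-like clusters had it too and its mean was 3927 FPKM in negative control wells and 4147 in fibroblast-like cells. Every cluster had at least 6 of 15 fibroblast markers in at least 25% of its cells, so each would have met the fibroblast rule. Fibroblast markers were lower in the basal-like cluster, with a median ratio of 0.206 to fibroblast-like cells. Of 10 clusters, 8 were named fibroblast-like, 1 luminal epithelial-like and 1 basal epithelial-like, by markers fixed before the data were examined and a naming rule set afterwards. The basal-like cluster had 5 basal and 5 luminal markers raised, so its name came from the order in which ties were read. Fibroblast-like clusters held 1092 of 1170 cells, or 93.3% (91.7 to 94.7). The luminal-like cluster held 63 cells, 5.38% (4.16 to 6.84), and the basal-like cluster 15 cells, 1.28% (0.719 to 2.11). Markers could enter the clustering, so their levels define the clusters and are not results.

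No cluster was named smooth muscle-like, so 0 of 1170 cells bore that name. The 0 comes from a rule on clusters and sets no limit on the share of single smooth muscle cells. Acta2, the actin of smooth muscle, was detected in 12.1% of kept cells (10.3 to 14.1), Tagln in 13.6%, Des in 17.8% and Myh11, the smooth muscle myosin heavy chain, in 3.76%. These transcripts were scattered over cells: 6 of 1170 cells had at least 7 of the 14 smooth muscle markers and 1 had 9. The planned comparisons of smooth muscle-like with fibroblast-like cells, and among smooth muscle-like clusters, therefore had no cells to run on. In 5 alternatives, a pericyte-like cluster of 13 to 23 cells had 3 or 4 smooth muscle markers raised. With at least 300 detected genes (23 cells) and with another random start (13 cells), 3 smooth muscle and 3 pericyte markers were raised, and the name pericyte-like came only from the order in which ties were read.

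**Figure D2:**
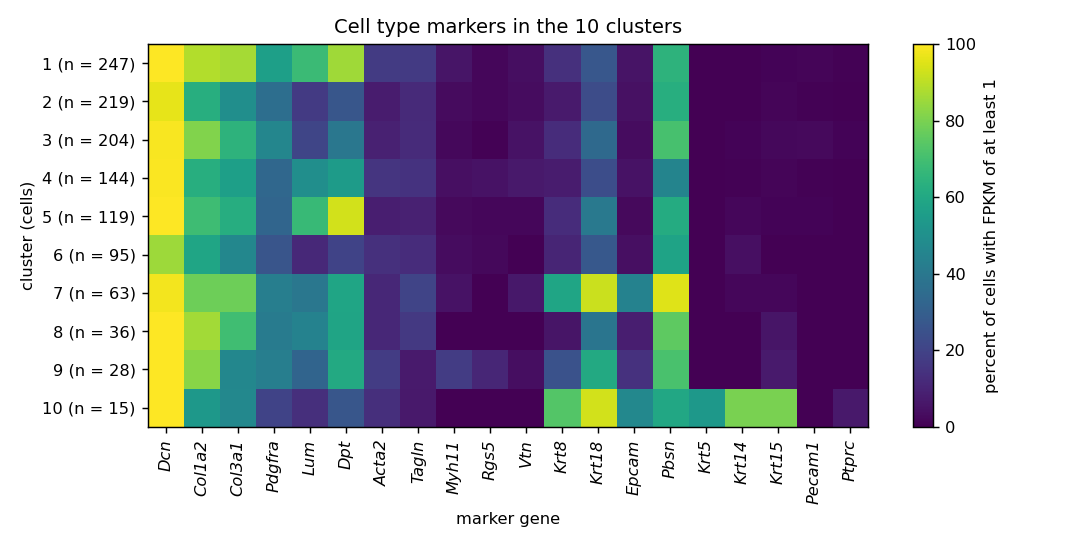
Percent of cells with an FPKM of at least 1 for 20 marker genes (columns) in the 10 clusters (rows, with their number of cells). Dcn is near 100 in all clusters but cluster 6, Krt5, Krt14 and Krt15 are high only in cluster 10, Krt8, Krt18 and Epcam are highest in clusters 7 and 10, and Pbsn is highest in cluster 7.

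Transcripts of cells that the sort should have removed were rare, apart from epithelial ones. Pecam1, an endothelial adhesion molecule, was detected in 0.940% of kept cells (0.470 to 1.68) and Ptprc, the pan-leukocyte antigen CD45, in 0.342% (0.0932 to 0.873). Cd24a, which encodes CD24, was detected in 12.1% (10.3 to 14.1), with 34 of 63 cells in the luminal-like cluster, and Itga6, which encodes CD49f, in 2.14% (1.39 to 3.14). Both were at 2.08% in negative control wells, with an upper limit of 11.1%. Marker and gate genes other than the fibroblast markers numbered 98. Of these, 8 had an interval in kept cells wholly above that of the negative control wells: Des, Smtn and Mylk of contractile cells, Pdgfrb of pericytes and fibroblasts, the keratins Krt8 and Krt19, the luminal gene Pbsn, and Wt1, listed as a mesothelial marker and found in 21.2% of kept cells. The wells differed in depth, and at 1000 reads on genes per well the number was 0. Only 24 negative control wells remained there, where even a gene found in none has an upper limit of 14.2%. Genes in few kept cells could not pass that limit, so the 0 does not show that depth made the 8.

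Secretory transcripts of the prostate were found in wells of every kind. Sbp, which encodes a spermine-binding protein, was detected in 99.8% of kept cells and 95.8% of negative control wells, at mean FPKM of 8554 and 9387. Spink1, a protease inhibitor, was detected in 98.0% and 79.2%, at 12283 and 14352. Pbsn, which encodes probasin, reached 64.2% and 39.6%. Svs4, a seminal vesicle secretory gene, went the other way, with 11.3% of kept cells against 35.4% of negative control wells (22.2 to 50.5). Of 16 secretory genes, a list without Pbsn, only Spink1 had an interval wholly above that of the negative control wells. At 1000 reads per well, with 24 negative control wells left, none did. Fibroblast transcripts such as Dcn were also present there. FPKM is a share of reads, so a like FPKM in a negative control well, with a median of 1543 reads, stands for far fewer reads than in a kept cell, with a median of 46690.5. The means of the negative control wells are given below beside those of the clusters for some genes only. The other contrasts between clusters are not set against that background.

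Within the fibroblast-like cells, Srd5a2, Wnt2 and Wif1 were opposite to C3, C7 and Cxcl1 in clusters 3 and 5. This is a contrast of single genes: the Wnt list and the list with Srd5a2 lay inside the central 95% of 10000 random lists in all 8 fibroblast-like clusters, and the complement list lay outside in clusters 2 and 4 only. Srd5a2, the steroid 5-alpha reductase that makes dihydrotestosterone, averaged 85.6 FPKM in cluster 3 (204 cells) and 65.9 in cluster 2 (219 cells, where it was not past the size rule), against 3.11 in cluster 4 (144 cells) and 0.224 in cluster 5 (119 cells). It was detected in a minority of cells: 21.6% in cluster 3 (16.1 to 27.9), 14.2% in cluster 2, 2.78% in cluster 4 and 0.840% in cluster 5. The Wnt ligand Wnt2 averaged 157 FPKM in cluster 3 and 11.7 in cluster 5, and the secreted Wnt inhibitor Wif1 519 and 37.7. Complement component C3 averaged 150 FPKM in cluster 5 and 6.83 in cluster 2, and the neutrophil chemokine Cxcl1 8071 and 783. Negative control wells had means of 21.2 FPKM for Srd5a2, 64.3 for Wnt2, 597 for Wif1, 16.8 for C3 and 1746 for Cxcl1. Among genes named again below, they had 119 for C7, 461 for Ccl11, 333 for Cxcl13, 157 for Mmp2 and 79.6 for Sfrp2. Those of Wif1 and Sfrp2 lay above the means of all clusters. The function genes were kept out of the clustering. In mm10 coordinates of the files, Srd5a2 spans 74017706 to 74047916 on chromosome 17, Wnt2 17988940 to 18030445 on chromosome 6, C3 57203967 to 57228136 on chromosome 17 and Cxcl1 90891245 to 90893115 on chromosome 5.

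**Figure D3:**
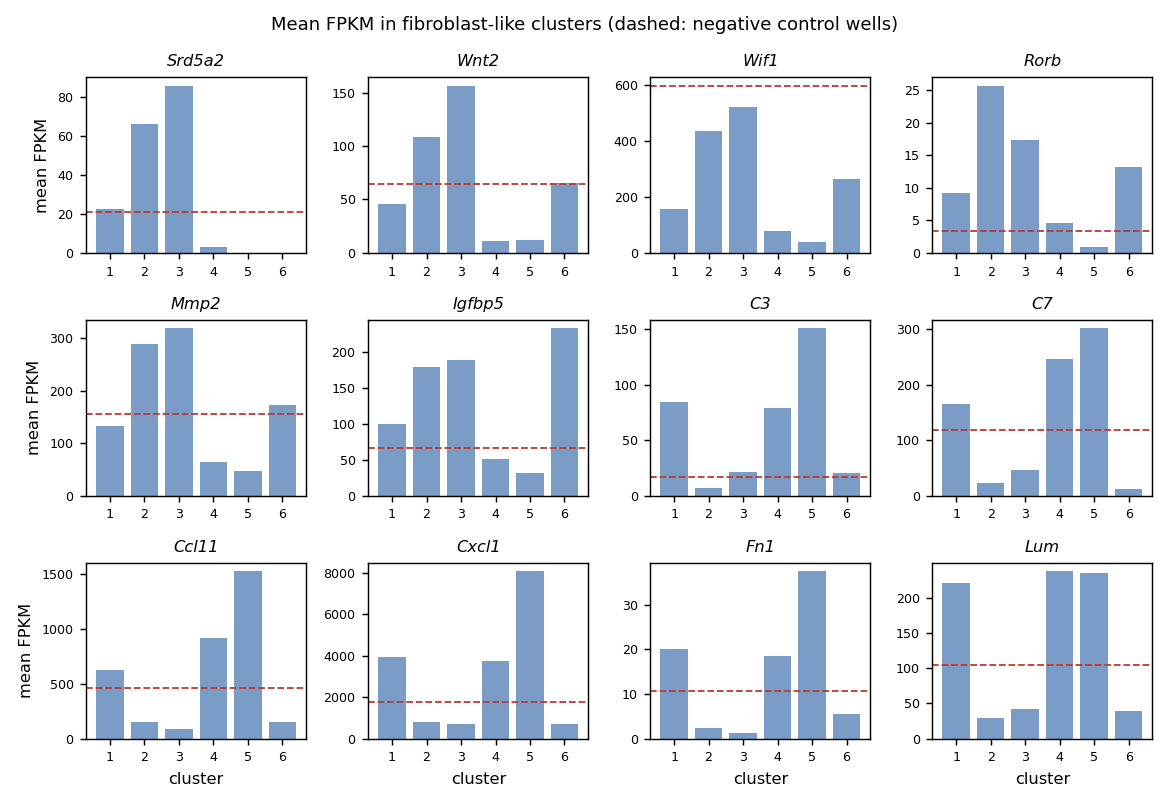
Mean FPKM of 12 genes in fibroblast-like clusters 1 to 6 (bars), with the mean of the negative control wells as a dashed line; each axis starts at 0. Srd5a2, Wnt2, Wif1 and Mmp2 are highest in clusters 2 and 3, and C3, C7, Ccl11, Cxcl1 and Fn1 are highest in cluster 5.

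Cluster 5 had the most genes past the size rule, 20 higher and 29 lower of 362 function genes, relative to the other fibroblast-like cells. Of 19 chemokine and cytokine genes, 6 were higher, among them Cxcl1 (8071 against 2061 FPKM), the eosinophil chemokine Ccl11 (1522 against 401) and the B cell chemokine Cxcl13, and 3 were lower, among them Cxcl14 (30.8 against 173). The complement genes C3 (150 against 44.4), C7 (302 against 99.9) and C4b (12.4 against 3.49) were higher. The matrix genes Fn1 (37.5 against 10.4) and Col14a1 (10.3 against 2.55) were higher. Lower were Srd5a2 (0.224 against 41.4), Wnt2 (11.7 against 82.7), Wif1 (37.7 against 307), Sfrp2, Dkk3, the IGF binding proteins Igfbp3 and Igfbp5, the gelatinase gene Mmp2 (47.5 against 205) and Bmp4. The transcription factor genes Isl1 (21.1 against 61.3), Rorb (0.869 against 14.8), Osr2 and Nr2f1 were lower too. The chemokine list had a median log2 ratio of 0.55 (percentile 100 among 10000 random lists), against -0.26 for all genes, but with cells weighted by their reads it was -0.15 at percentile 45.6. The stromal transcription factor list had -0.80 (percentile 0.30) and the immediate early and stress list -0.56 (percentile 0.07).

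Cluster 3 showed much of the opposite pattern. Higher were Srd5a2 (85.6 against 25.7 FPKM), 4 of 23 Wnt genes, namely Wnt2 (157 against 56.2), Wif1 (519 against 222), Wnt10a (22.3 against 4.58) and Wnt5b (5.02 against 1.76), the growth factor genes Gdnf, Nrg1 and Ptn, Thy1 (65.2 against 29.4), Bmp7 and Mmp2 (319 against 158). Some of these higher means rest on few cells. Wnt10a was detected in 7.84% of cluster 3 (2.14% of the others), Wnt5b in 5.39% (1.58%), Nrg1 in 5.39% (1.46%) and Gdnf in 9.80% (2.70%). Lower were 5 chemokine and cytokine genes, among them Ccl11 (83.8 against 624), Cxcl1 (722 against 3174) and Cxcl13 (116 against 605), the complement genes C3 and C7, and the matrix genes Fn1 (1.28 against 16.1), Postn and Ogn. In all, 11 function genes were higher and 16 lower. The chemokine list had a median log2 ratio of -0.73 (percentile 0.00), the interstitial matrix list -0.36 (percentile 0.08) and the lipid and retinoid list -0.70 (percentile 0.00), against 0.01 for all genes. Mmp2 and Bmp7 ran against their lists: matrix remodelling had -0.31 (percentile 0.08), and TGF-beta and BMP signalling -0.20 (percentile 2.02), which lay inside in every alternative. The Wnt list as a whole, with a median of 0.00 at percentile 68.3, did not stand apart.

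Cluster 2 had few genes higher and many lower. Rrm2, a subunit of ribonucleotide reductase, averaged 185 against 58.7 FPKM and Rorb 25.7 against 10.2. Lower were 8 of 19 chemokine and cytokine genes, including Cxcl13 (25.7 against 636), Cxcl1 (783 against 3201) and Ccl7 (2477 against 8075), and 4 of 14 complement genes, including C3 (6.83 against 68.2) and C7 (22.4 against 147). The chemokine list had a median of -1.10 (percentile 0.00), the complement list -0.57 (percentile 0.21) and the lipid and retinoid list -0.59 (percentile 0.09). The stromal transcription factor list had 0.29 (percentile 99.02), which became -0.0046 with the difference of mean log2(FPKM + 1). In all, 2 function genes were higher and 23 lower. The median of 31639 mapped reads per cell was below the 46690.5 of all kept cells.

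Wnt2, Wif1 and Sfrp2 were low in cluster 4 as in cluster 5, although the Wnt list lay inside the random lists in both (percentiles 2.92 and 8.93). In cluster 4, Wnt2 averaged 11.6 against 84.6 FPKM, Wif1 77.7 against 308, Sfrp2 10.2 against 52.2, Srd5a2 3.11 against 42.1, Mmp2 64.4 against 207 and Igfbp5 50.8 against 147. Only C7 (247 against 103) and Sparcl1 (465 against 213) were higher, and 15 function genes were lower. The chemokine list had a median of 0.34 (percentile 100) although none of its members was higher past the rule and Cxcl14, Cx3cl1 and Il34 were lower. The immediate early and stress list had 0.16 (percentile 99.98). With the difference of mean log2(FPKM + 1) it had -0.20 against -0.099 for all genes, while its percentile stayed at 99.98. Its direction against all genes is thus not settled. Pbsn was lower, 423 against 1108 FPKM, and both lay below its mean of 1665 in negative control wells. At 26968 mapped reads the median cell was shallow, and 13 cells that were called pericyte-like at a higher clustering resolution lay in this cluster.

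Cluster 1, the deepest with a median of 80119 mapped reads, had 8 function genes higher and 0 lower. Sfrp4, a secreted Wnt modulator, averaged 72.4 against 6.25 FPKM but was detected in 8.91% of its cells (5.67 to 13.2) against 2.25% of the others, and negative control wells had a mean of 61.8. The matrix genes Postn (in 25.9% of cells against 8.99%), Col8a1 and Col14a1, the retinaldehyde dehydrogenase gene Aldh1a3 (12.2 against 3.63), the protease inhibitor gene Timp1 (267 against 118), Ccl8 and Hoxa11 were also higher. Of the 12 function and marker genes of cluster 1 past the rule, 8 passed again with shares of cells thinned to equal reads on genes. Among those that did not were Hoxa11 (4.05% against 2.31%), Ccl8 (2.83% against 0.643%) and Col14a1 (7.29% against 3.34%). For the genes that did not pass again, the greater depth of cluster 1 stays open as a source of the higher shares. The chemokine list had a median of 0.48 (percentile 100), the interstitial matrix list 0.36 (percentile 99.9) and the stress list -0.22 (percentile 0.03). With the difference of mean log2(FPKM + 1) the stress list had 0.45 against 0.15 for all genes, while its percentile stayed at 0.03. Its direction against all genes is thus not settled. The Hox list had -0.24 (percentile 0.72), opposite to Hoxa11, which did not pass again at equal reads.

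Cluster 6 was the shallowest, with a median of 19558 mapped reads, and 34 of its 38 function genes past the rule were lower. Of its 44 function and marker genes past the rule, 26 passed again with shares at 10000 reads, where 65 of 95 cells remained, so depth and the smaller number of cells cannot be told apart. Ccl7 (1252 against 7495 FPKM), C7 (12.4 against 132), Ly6a (293 against 845), which encodes the antigen Sca-1, and Srd5a2 (0.197 against 40.4) were among the lower. Igfbp2 was higher (18.9 against 0.703), though detected in 7.37% of cells against 1.10%. Of the 4 genes counted as higher, 3, among them Ltbp4 and Zfp36, had a lower share of cells, so no order was read from them. Luminal markers had higher means too, namely Krt18 (344 against 120), Krt8 (59.2 against 15.2), Epcam (19.8 against 3.34) and Pbsn (2304 against 895), though not higher shares of cells. The stress list had a median of 0.45 (percentile 100) against -0.45 for all genes. With the difference of mean log2(FPKM + 1) it had -0.59 against -0.16, while its percentile stayed at 100. Its direction against all genes is thus not settled. Clusters 8 and 9 were led by near-identical 5S rRNA and histone H4 gene copies, whose reads cannot be assigned to single copies. Each had 1 function gene past the rule, Hsd11b1 (277 against 124) in cluster 8 and Jund (20.8 against 9.41) in cluster 9, where the luminal keratin Krt18 was also higher (678 against 126). With shares at 10000 reads, Hsd11b1 did not pass again, and 1 of the 2 function and marker genes of cluster 9 did. Cluster 9 also had more secretory RNA, with means of 25536 FPKM for Sbp, 37258 for Spink1 and 6934 for Pbsn against 6994, 10624 and 1018 over all fibroblast-like cells, and 2 luminal markers raised. Its name and its low chemokine list are to be read with that excess in mind.

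**Figure D4:**
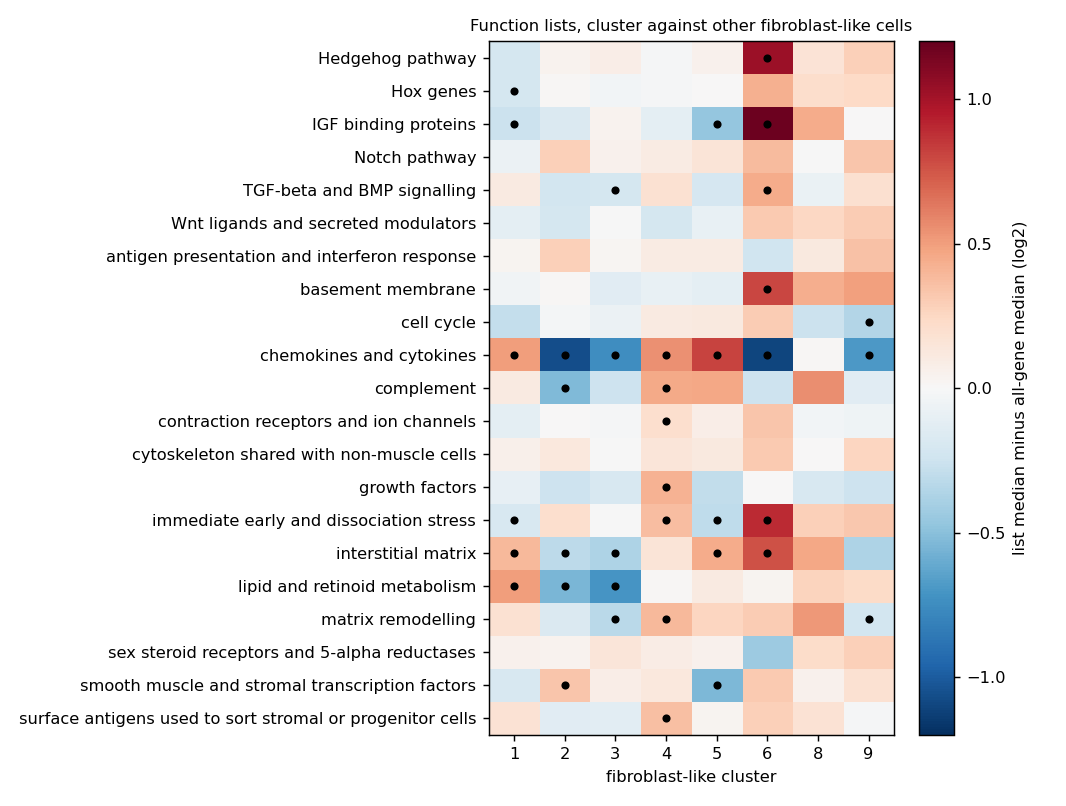
Median log2 ratio of each of 21 function lists (rows) minus the median of all genes, for each fibroblast-like cluster against the other fibroblast-like cells (columns); dots mark lists outside the central 95% of 10000 random lists. The chemokine and cytokine list is marked in 7 of the 8 clusters, above in 1, 4 and 5 and below in 2, 3, 6 and 9.

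Across the 8 fibroblast-like clusters, 38 of 168 pairs of a list and a cluster lay outside the central 95% of the random lists. The percentiles alone would give 8.40 if the genes of a list varied independently. Such genes can vary together, and each cluster is part of the reference of the others, so the size of the excess is not known. Of the 38 pairs, 19 were above and 19 below, and 13 lay outside on the same side in every alternative that was fixed before the data were examined and run on these pairs. The cluster borders themselves depended on the settings, since the adjusted Rand index between the fibroblast-like clusters and those of other settings was 0.31 to 0.65, and 0.85 with another random start. Simulated cells of 1 unchanged kind with the real depths were also divided into 5 clusters of at least 20 cells, so a number of clusters is no count of cell types. There, 2 of 105 pairs lay outside the percentiles, but each gene was varied independently, so this does not show what genes varying together would give.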

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

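The look at S wells left out of the clustering, and all tests weighed in this part except the one on wells holding both fibroblast and luminal transcripts, were chosen after the results were seen.

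Among the S wells with too few detected genes, 1 well had 7 of 14 smooth muscle markers, against at most 2 in any control well: Acta2 at 3313 FPKM, Tagln at 3864, Myh11 at 350, Cnn1, Des, Myl9 and Mylk, with Dcn at 0. It held 3585 mapped reads and 387 detected genes. Another had 7 of 10 luminal markers, against at most 4 in a control well, with Pbsn at 3738 FPKM, Krt18 at 1193 and 7067 mapped reads. No control well had a blood endothelial or glial marker, and 8 and 5 of the 153 wells left out had at least 1. The highest were Cdh5 and Flt1 in a well of 23344 mapped reads and Sox10 and Cdh19 in a well of 7112. Control wells had at most 3729 mapped reads, so only the smooth muscle well compares with them at like depth.

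Fibroblast transcripts were high in the luminal-like cluster. The median ratio of its fibroblast markers to those of fibroblast-like cells was 0.732, above the upper quartile of 0.419 in the basal-like cluster, which argues against RNA shared by all wells as the whole source. Of 52 wells of the cluster with at least 2 luminal markers, 73.1% (58.98 to 84.4) also held at least 2 of 5 fibroblast markers at 10000 reads, close to 70.5% of fibroblast-like cells and above 28.6% (8.39 to 58.1) in the basal-like cluster. Wells that hold a fibroblast and luminal RNA together may therefore account for much of this cluster. Fibroblasts with more of the common secretory RNA stay open too, because the luminal markers define the cluster and cannot test it. No biological explanation was tested.

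Transcripts of prostate cells were present in negative control wells. Whole cells are argued against by their depth, with a highest well of 3729 mapped reads against a median of 40678 in S wells. If reads of S wells had been assigned to them in proportion, 10 genes used by nearly every cell should take 1.29% of reads, and they took 1.11%, below all of 100 draws (1.16 to 1.40). Because reads of few molecules are not independent, the negative wells were also resampled, which gave 0.965 to 1.26, again below 1.29. Proportional assignment as the whole source is thus argued against by a small margin; assignment that is not proportional, or free RNA, stays open and could each contribute.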

How the results depend on the processing

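Alternatives on random starts, multicopy and secretory genes, caps, read weights and thinning were chosen after the data were seen. The share of S wells kept was 94.8% with at least 300 detected genes, 62.1% with at least 1000 and 91.2% above the 95th percentile of the negative control wells, by construction. The fibroblast-like share and that of other clusters were 90.9% and 9.09% with at least 300 genes, 90.3% and 9.73% with at least 1000, 95.3% and 4.70% with log2(FPKM + 0.1), 95.2% and 4.79% with 30 principal components, and 98.7% and 1.28% at Leiden resolution 0.5, where no luminal-like cluster was found. The smooth muscle-like share stayed at 0 in every setting run, by ties with the pericyte list in 2 of them; in 3 more, a cluster with 3 or 4 smooth muscle markers raised had more pericyte markers. The planned comparisons of smooth muscle-like cells were not run, as no cell was in that class. Pairs of a list and a cluster outside the percentiles numbered 24 in chip columns 36 to 71 and 29 to 44 in the other alternatives. Fewer cells entered in columns 0 to 35 as well, so the 24 cannot be put down to the number of cells alone. Thinned to 1000 reads on genes, fibroblast markers aside, 0 gate or marker genes had an interval wholly above that of the negative control wells. The number for secretory genes was 0 too. There 24 negative control wells remained, so their interval reached 14.2% even for a gene found in none. Of the fibroblast markers, Col3a1 (29.7% of kept cells against 4.17%) and Col1a2 (31.2% against 8.33%) were wholly above. Named genes and list medians kept the main clusters under the alternatives and were not recomputed under other clusterings. Of values of named genes, 1041 stayed past a log2 ratio of 1, 140 did not and 0 changed sign. In the parts of the chip no change of sign was possible, because the rule for named genes required the same direction there. Of list medians, 216 stayed outside on the same side and 66 did not, without a change of sign, and 19 changed sign, of which 6 stayed outside on the same side. These 6, with the difference of mean log2(FPKM + 1), were 0.45 for stress genes in cluster 1 (percentile 0.03), -0.0046 for stromal transcription factors in cluster 2 (99.56), -0.016 for growth factors (97.77), -0.20 for stress genes (99.98) and -0.096 for matrix remodelling (98.82) in cluster 4, and -0.59 for stress genes in cluster 6 (100). The others lay inside the random lists. With the same difference they were 0.40 for IGF binding proteins in cluster 1 (4.03), -0.28 for surface antigens in cluster 4 (36.09), and -0.32 for basement membrane (8.99) and -0.28 for interstitial matrix (50.39) in cluster 6. In columns 0 to 35 they were -0.058 for growth factors in cluster 4 (85.74) and -0.13 for interstitial matrix in cluster 6 (93.7). In columns 36 to 71 they were -0.11 for growth factors (88.42), -0.18 for matrix remodelling (52.89) and -0.085 for surface antigens (80.11) in cluster 4 and -0.013 for interstitial matrix in cluster 5 (90.92). With cells weighted by reads they were -0.043 for surface antigens in cluster 4 (85.82), and -0.15 for chemokines (45.63) and -0.030 for interstitial matrix (86.97) in cluster 5. The cause was not tested. No paired analysis was possible because the well numbers name wells only and pair none across groups.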

Other observations

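The tests and observations of this part were chosen after the results were seen.

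At a higher clustering resolution, 14 cells formed a cluster with pericyte markers. Vtn was detected in 57.1% of them (28.9 to 82.3) against 3.03% of the other kept cells, and Kcnj8, Abcc9, Rgs5 and Higd1b in 28.6% each. Acta2 (7 of 14 cells against 11.7%) and Myl9 (57.1% against 10.99%) were raised too. All these markers could enter the clustering, so their levels define the cluster and are not results. Of genes kept out of the clustering, the endothelin receptor genes Ednra (35.7% against 1.82%) and Ednrb (35.7% against 8.04%) were more frequent.

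A single S well of the luminal-like cluster, at chip row 1 and column 36, held 97.9% of all Svs4 reads of the S wells. Its 242440 mapped reads put 57.7% of the reads on genes on 6 Svs genes, with Svs5 at 511173 and Svs4 at 451968 FPKM, while Pbsn was at 43.6 and Dcn at 185. The Svs means of that cluster rest on this well. Svs4 was nonetheless detected in 35.4% of negative and 32.6% of positive control wells, against 10.5% of S wells. Summed over wells, its level was 1689 RPM (reads scaled to a common total) in the negative control wells and 1066 RPM in the S wells. Svs4 was found in 0 of 7 other wells of the same chip row, 1 of 29 of the same column and 169 of 1380 elsewhere. The wells elsewhere include all control wells, where Svs4 was more frequent, and that row and column hold none. These shares are therefore not of like wells.

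Srd5a2, Wnt2 and Wif1 were opposite to C3, C7 and Cxcl1 in clusters 3 and 5. Past the size rule, cluster 2 shared the low C3, C7 and Cxcl1 only, and cluster 4 the low Srd5a2, Wnt2 and Wif1 and the high C7. These patterns of clusters 2 to 5 were weighed against technical sources. A difference in reads per cell is argued against as the source of the differing shares of cells. Of 140 list genes past the size rule, counted once per cluster, 126 (90%) passed again with shares at 10000 reads. Ratios of mean FPKM and the clusters themselves stayed those of all reads, so clusters drawn along depth stay open. Place by chip columns is argued against for the cells: no such cluster had over 60.8% of its cells in columns 0 to 35 or in the other columns. The genes had been chosen for the same direction in both parts, so they cannot speak to it. Rows and finer places on the chip were not weighed. Stronger induction of stress genes during dissociation was weighed as 1 cause of the high chemokine and complement genes. It is argued against in cluster 5, where the stress list lay at percentile 0.07, with 1 member higher and 3 lower past the rule. The list cannot speak to a response to dissociation in genes outside it, such as the chemokine genes themselves. In cluster 4, where C7 was the only gene of those lists higher past the rule, the stress list lay at 99.98 and induction stays open. The percentiles compare the clusters with each other, so induction in all of them was not weighed. No biological explanation was tested.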
